A study of Felis catus with 6 samples.

How the data were processed

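The 6 small RNA libraries came from F81 cells, 3 flasks infected with FPV and 3 uninfected, harvested 48 h after infection. Per the labels, total RNA was extracted with Trizol, libraries were made with a TruSeq small RNA kit and sequenced on an Illumina instrument. Per the labels, the authors filtered reads with ACGT101-miR, which removed adapter dimers, low-complexity reads, repeats, and reads of ribosomal, transfer, small nuclear and small nucleolar RNA. Some entries that overlap such RNAs are still listed. The mapping, the miRBase release, the genome build and the formula of the normalization are not given in the sources used here.

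The deposited values are a normalized signal, headed as normalized in the file, with 1 column for each library. They are not whole numbers, and the column totals differ, so they are neither counts nor per-million values. Of values up to 30, between 98.6% and 99.6% in a library lay within 0.1 of a whole multiple of 1 step for that library, which was 0.335, 0.416 and 0.423 in uninfected and 0.527, 0.582 and 0.863 in FPV replicates 1 to 3. Of those, 82.6% to 88.6% were even multiples. A step may thus be a read shared evenly by 2 entries, so 1 read was taken as 2 steps for the estimated depth. Were 1 step a whole read, each depth would be 2 times higher and their ratio the same. Some values are fractions of a step and the smallest listed value is several steps, so the values were not taken as recovered read counts and no count test was run. The smallest listed values are 3.33 to 5.00 steps, or 1.67 to 2.50 reads on that estimate, so that a 0 may stand for a read or more, and in normalized units the smallest value of FPV replicates 2 and 3, at 2.91 and 2.88, lies above that of every other library.

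The file has 1178 rows, of which 149 repeat a sequence listed earlier with the same values, 119 of them as exact repeats. As fixed before the data were examined, every row was fitted. Of 586 rows tested 156 passed, and all counts in the text are of distinct sequences, with the first row standing for a repeated one. For hairpin strands and shares each distinct sequence was added once, under the first name listed. Of the 497 tested, 5 have the values of another tested sequence in every library and may be the same reads. None of the 5 passed, and a fit that holds such entries once was added. Sequences shared by paralogous hairpins cannot be assigned to 1 of them. All 6 value columns matched a sample title.

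The plan fixed before the data were examined named a quasi-likelihood count test for raw counts and limma for normalized values, and the second was used. Values were transformed as log2(value + 1), and rows with a value of at least 10 in at least 3 libraries were kept. Limma 3.58.1 in R 4.3.3 was run with a mean-variance trend and group as the only term, and p-values were adjusted by Benjamini-Hochberg at 0.05. On this scale the added 1 pulls the change of low entries toward 0. A library listed at 0 can instead make the change larger than the fold of group means. For example, hsa-miR-16-1-3p_R+1 was at -3.18 on this scale and at 0.149 as a ratio of group means, FPV over uninfected. Folds of group means are of the deposited values, and no fold is given against a group listed at 0.

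The 19 lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, for the 17 lists with at least 3 tested distinct members, and again with an estimated correlation and with fry. Repeated rows counted as members in these tests. The 3 lists called by camera thus entered with more rows than distinct members: 19 for 16 in miR-17-92, 12 for 11 in miR-99/100 and miR-125, and 11 for 8 in miR-181. The 3 camera calls did not hold with an estimated correlation. The miR-200 and hepatic lists had 1 tested member each and were not tested as lists. The 5p to 3p ratio used a pseudocount of 0.5, strands with a mean of at least 10 over the 6 libraries, and limma without a trend. Shares were compared by an exact permutation test. The entries grouped as overlapping structured RNAs were chosen from background knowledge after the values were seen, and were not checked against a genome.

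Named entries follow a rule fixed before the data were examined. It takes the 12 known entries with the largest rise and the 12 with the largest fall among those with adjusted p under 0.05, a mean of at least 10 and no overlap between groups. It adds up to 3 predicted entries each way by the same rule, the 10 most abundant entries, up to 4 most abundant tested members of each list and the 6 hairpins with the smallest p. Entries outside the rule are marked as chosen after their values were seen.

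The procedure was tested on simulated data with the real means, reads worth 2 steps, and 200 entries changed for FPV against uninfected. All entries had 1 common spread between libraries (dispersion 0.0130), so real entries that vary more were not modelled. Of those that passed the filter, among 532 tested in all, it recovered 78.5% of 65 changed 1.5-fold, 90.9% of 66 changed 2-fold and 100% of 64 changed 4-fold, and 2.23% of calls were false. A list shifted by 1.5-fold was called among 17 others with none of these called, and no list was called with nothing changed. Entries were drawn independently, so the simulation cannot check the preset correlation on which the list calls rest. Of 18 hairpins with a changed strand 16 were recovered among 119, with 2 false calls.

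Alternatives covered the pseudocount, the filter, quantile normalization, TMM scaling, equal totals, the replicate number as a block, sums over forms of a name, known miRNAs only, the most abundant miRNA left out and each library left out. After the data were seen, fits of distinct sequences, of entries with identical values once, without predicted entries listed at 0 in uninfected cells and without structured RNA names were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.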

Results

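Small RNA was sequenced from F81 cells, a cell line from cat kidney, with and without infection by feline panleukopenia virus (FPV), a parvovirus with a small single-stranded DNA genome. The labels name 3 flasks infected and 3 left uninfected, harvested 48 h after infection, with 1 library from each flask. The labels do not say whether the flasks came from separate passages, so p-values measure the spread between flasks. The deposited table lists a normalized read number for each small RNA sequence in each library. It holds 1029 distinct sequences, 760 under names of known miRNAs with a species prefix and 269 listed as predicted. Summed over distinct sequences, the libraries held 3.12, 3.15 and 3.26 M normalized reads in uninfected replicates 1 to 3 and 2.93, 2.91 and 3.11 M in FPV replicates 1 to 3. The files give no raw depth. With 1 read taken as 2 of the smallest steps between low values, the sums correspond to 4.65, 3.78 and 3.85 M reads in the uninfected libraries and 2.78, 2.50 and 1.80 M reads in the FPV libraries. On this estimate every FPV library held fewer reads in the listed entries than every uninfected library, with a ratio of the group means of 1.73. Reads filtered out or not listed are not in the estimate, so the depth of a whole library is not known. Depth below means this estimate. Correlations of log2 values ran from 0.954 to 0.983 between libraries of a group and from 0.834 to 0.874 between libraries of different groups.

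The comparison of infected with uninfected cells asks which miRNAs differ in abundance 48 h after infection. FPV-infected cells had more of several short RNAs named as miRNAs that overlap ribosomal RNA, led by bta-miR-2887_L+1R+4. They had less of the minor strands of several abundant hairpins, led among entries at a mean above 100 by hsa-miR-92a-1-5p and hsa-miR-27b-5p. A set of predicted sequences was listed at 0 in every uninfected library and above 0 in every FPV library. The most abundant miRNA, hsa-miR-21-5p_R+1, was at 797799 ± 18719 in uninfected cells and 726453 ± 42391 in FPV-infected cells (SD, n = 3 each), a difference of -0.14 ± 0.07 (SE) on the log2(value + 1) scale that did not pass the test (adjusted p = 0.189). Of 497 distinct sequences tested with limma, 142 passed an adjusted p of 0.05, with 72 higher and 70 lower in FPV-infected cells. Among the known miRNAs 41 were higher and 64 lower, and among predicted sequences 31 were higher and 6 lower. The groups did not overlap for 232 sequences, or 46.7% of those tested, where chance gives 10%. These include 30 predicted and 1 known entries listed at 0 in all uninfected libraries, whose separation was fixed by the filter. Without FPV replicate 1 the count was 58, with 15 higher and 43 lower, and without uninfected replicate 1 it was 79, with 31 lower. The number lower was 40 without uninfected replicate 3, and the number higher was 36 without FPV replicate 2 and 33 without FPV replicate 3. The minimum of 10 in 3 libraries was kept in these fits. Entries listed at 0 in all uninfected libraries thus could not be tested without an FPV library, which lowers the number higher. Without FPV replicate 1, 457 sequences were tested. With known miRNAs only 37 were higher, and 27 once names that overlap structured RNAs were also left out. Where several libraries or settings are named for a result, each was left out or changed in turn.

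**Figure D1:**
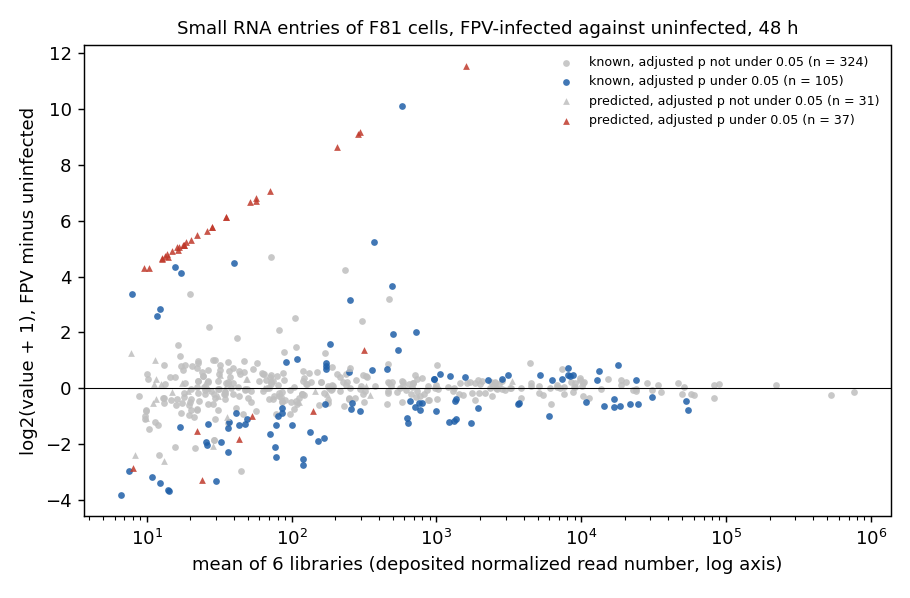
Each point is 1 distinct sequence, with its mean over the 6 libraries on a log x axis and its difference in log2(value + 1) between the FPV and uninfected groups (n = 3 each) on the y axis, known miRNAs as circles (105 changed) and predicted sequences as triangles (37 changed). The diagonal of triangles at the upper left holds sequences listed at 0 in all uninfected libraries, whose height reflects their level and the pseudocount of 1.

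Of the 12 known entries with the largest rise, 8 carry names that overlap other structured RNAs. Entry names follow the authors' file, where by convention L and R give bases added or missing at the ends and ss gives substitutions. The sequence bta-miR-2887_L+1R+4, whose name overlaps ribosomal RNA, was at 18.9 ± 7.18 in uninfected cells and 719 ± 97.5 in FPV-infected cells (SD, n = 3 each), a rise of 5.24 ± 0.31 (SE, adjusted p = 4.29e-05). From the same class, bta-mir-2904-2-p3 was at 49.4 ± 1.33 in uninfected cells and 459.8 ± 145 in FPV-infected cells (adjusted p = 0.000106), and bta-mir-2904-2-p5 was 3.76-fold higher in group means (adjusted p = 0.00314). A form of miR-1246, whose name overlaps U2 small nuclear RNA, hsa-miR-1246_L+2_1ss19AC, was at 69.1 ± 5.00 in uninfected cells and 912 ± 291 in FPV-infected cells (adjusted p = 6.48e-05). The entry hsa-mir-6516-p3 rose 4.04-fold, to 1163 ± 222 (adjusted p = 0.000157). Largest of all was ssc-mir-4332-p3_1ss16CA, listed at 0 in the 3 uninfected libraries and at 1228, 807 and 1412 in the FPV libraries (adjusted p = 1.44e-06). The others were eca-mir-8986a-p3_1ss17CT, hsa-miR-4508_L+2R-1, bta-mir-2887-1-p3_1ss11TC, hsa-miR-1260a_R+3_1ss9TG, bta-miR-215_1ss13TC and hsa-miR-1246_L+1_1ss18AC, with adjusted p between 0.00213 and 0.0494.

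Names that overlap structured RNAs were grouped into 3 classes after the values were seen, and each class was then taken whole. Of 10 entries in the ribosomal RNA class 5 rose and none fell, with mmu-mir-6236-p3 at 302 ± 58.4 in uninfected cells and 789 ± 127 in FPV-infected cells (SD, n = 3 each, adjusted p = 0.00207). Of 11 entries in the small nuclear and nucleolar RNA class 4 rose, among them bta-mir-1246-p5_1ss21CT (adjusted p = 0.0133), and 1, bta-mir-1246-p5, fell, at -1.32 ± 0.33 (log2, SE, adjusted p = 0.0266). Of 6 in the transfer RNA class 1 rose, hsa-miR-1260a_R+3_1ss9TG. The bta-mir-1246-p5 forms and mmu-mir-6236-p3 were chosen after their values were seen. The ribosomal class held 0.319% ± 0.114 of normalized reads in uninfected cells and 0.636% ± 0.176 in FPV-infected cells. Most of that share came from forms of miR-6240, none of which passed (adjusted p from 0.0664 to 0.727). The largest, mmu-mir-6240-p5_1ss23GT, also chosen after its values were seen, was at 5668 ± 1984 in uninfected cells and 9104 ± 2919 in FPV-infected cells. The small nuclear and nucleolar class held 0.0362% ± 0.00568 and 0.101% ± 0.0192, and the transfer RNA class 0.0322% ± 0.00623 and 0.0307% ± 0.00966. bta-mir-1246-p5 did not pass without uninfected replicates 1 or 3 or FPV replicate 1 (adjusted p from 0.0801 to 0.0968). bta-mir-1246-p5_1ss21CT did not pass without FPV replicate 1 and with forms of a name summed (adjusted p from 0.0559 to 0.275). hsa-miR-1246_L+1_1ss18AC did not pass without FPV replicate 1 (adjusted p = 0.0552). hsa-miR-1260a_R+3_1ss9TG did not pass under quantile normalization (adjusted p = 0.0554). Summing all forms under a name turned hsa-miR-1260a_R+3_1ss9TG to -0.44 and bta-mir-1246-p5 to 0.38 (adjusted p = 0.282 and 0.275).

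Predicted sequences not named in miRBase made up 31 of the 72 higher entries, and 30 of those 31 were listed at 0 in all uninfected libraries. Such an entry was tested only if every FPV library was at 10 or more. All 30 passed, and so did the 1 known entry of this kind, ssc-mir-4332-p3_1ss16CA. The filter in effect set these calls, so their adjusted p-values add no separate support. The highest predicted one, PC-5p-941_4772, was listed at 0 in uninfected cells and at 3204, 1804 and 4631 in FPV replicates 1 to 3 (adjusted p = 1.70e-06). PC-5p-4142_745 stood at 511, 546 and 715 and PC-3p-2607_1327 at 579.8, 384 and 772, again with every uninfected library at 0 (adjusted p = 1.44e-06 and 3.49e-06). Counting untested entries too, 45 predicted sequences were above 0 in all FPV libraries and at 0 in all uninfected libraries, and 5 showed the opposite. Those 45 held 0.208%, 0.145% and 0.275% of normalized reads in the 3 FPV libraries. Their mean GC content was 34.0% against 45.8% for the other 224 predicted sequences, and 91.1% against 45.1% were 20 bases or shorter. Of the predicted sequences that fell, PC-3p-19256_96 was at 42.6 ± 9.24 in uninfected cells and 5.49 ± 4.92 in FPV-infected cells (adjusted p = 0.0313). PC-5p-20260_89 and PC-5p-13851_154 were at -1.83 and -1.53 on the log2 scale (adjusted p = 0.0104 and 0.0163). PC-3p-19256_96 did not pass with a pseudocount of 0.5 (adjusted p = 0.0549). PC-5p-20260_89 did not pass without FPV replicate 1 (adjusted p = 0.0519). PC-5p-13851_154 did not pass without uninfected replicates 1 or 3 or FPV replicate 1 (adjusted p from 0.0520 to 0.0728). The source of these sequences was not assigned, since no genome was used here.

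Of the 12 known entries with the largest fall, 10 are the less abundant strand of their hairpin, and 2, hsa-miR-33b-3p_R-1 and hsa-miR-365a-5p, had no opposite strand listed under their name. The passenger strand of miR-92a, hsa-miR-92a-1-5p, was at 208 ± 9.04 in uninfected cells and 31.6 ± 12.9 in FPV-infected cells (SD, n = 3 each), a change of -2.74 ± 0.29 (SE, adjusted p = 0.000504). The entry hsa-miR-27b-5p was at 203 ± 32.2 in uninfected cells and 35.6 ± 14.4 in FPV-infected cells (adjusted p = 0.00189), and hsa-miR-33b-3p_R-1 at 133 ± 23.0 in uninfected cells and 23.3 ± 2.89 in FPV-infected cells (adjusted p = 0.000259). Changes of -2.28, -2.12 and -1.94 were found for hsa-miR-181b-3p, hsa-miR-29b-1-5p and hsa-miR-128-1-5p (adjusted p = 0.000594, 0.00572 and 0.00535). The other 6 lay at uninfected means of at most 52.3, where the smallest listed value of an FPV library is already 2.11 to 2.91. Their adjusted p ran from 0.0128 for hsa-miR-365a-5p to 0.0465 for sha-mir-24-1-p5_1ss2GC. Other minor strands of miR-16, miR-24 and miR-29b, chosen after their values were seen, did not pass. In uninfected and FPV-infected cells hsa-miR-16-2-3p_L+1R-1_1ss11CT was at 189 ± 29.0 and 197 ± 21.1 (adjusted p = 0.811). For hsa-miR-24-2-5p_L+1R+1 the values were 306 ± 68.3 and 243 ± 59.6 (adjusted p = 0.343). The change of hsa-miR-29b-2-5p_R+1 was -0.21 (adjusted p = 0.667). hsa-miR-1343-5p_1ss19TC did not pass without FPV replicates 2 or 3 (adjusted p = 0.0582 and 0.0607). hsa-miR-26a-1-3p did not pass without FPV replicates 1 or 3 (adjusted p = 0.0968 and 0.0607). hsa-miR-23b-5p_L-1 did not pass without FPV replicates 2 or 3, with no minimum, without predicted entries at 0 in uninfected cells and without structured RNA names (adjusted p from 0.0501 to 0.0836). sha-mir-24-1-p5_1ss2GC did not pass without uninfected replicates 1, 2 or 3 or FPV replicate 2, with a pseudocount of 0.5, with no minimum, with known miRNAs only, without predicted entries at 0 in uninfected cells and without structured RNA names (adjusted p from 0.0503 to 0.129). hsa-miR-16-1-3p_R+1 did not pass without FPV replicates 2 or 3, with a pseudocount of 0.5, with no minimum, with known miRNAs only, without predicted entries at 0 in uninfected cells and without structured RNA names (adjusted p from 0.0536 to 0.111). hsa-miR-365a-5p did not pass without uninfected replicates 1 or 2 (adjusted p = 0.0606 and 0.0508).

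**Figure D2:**
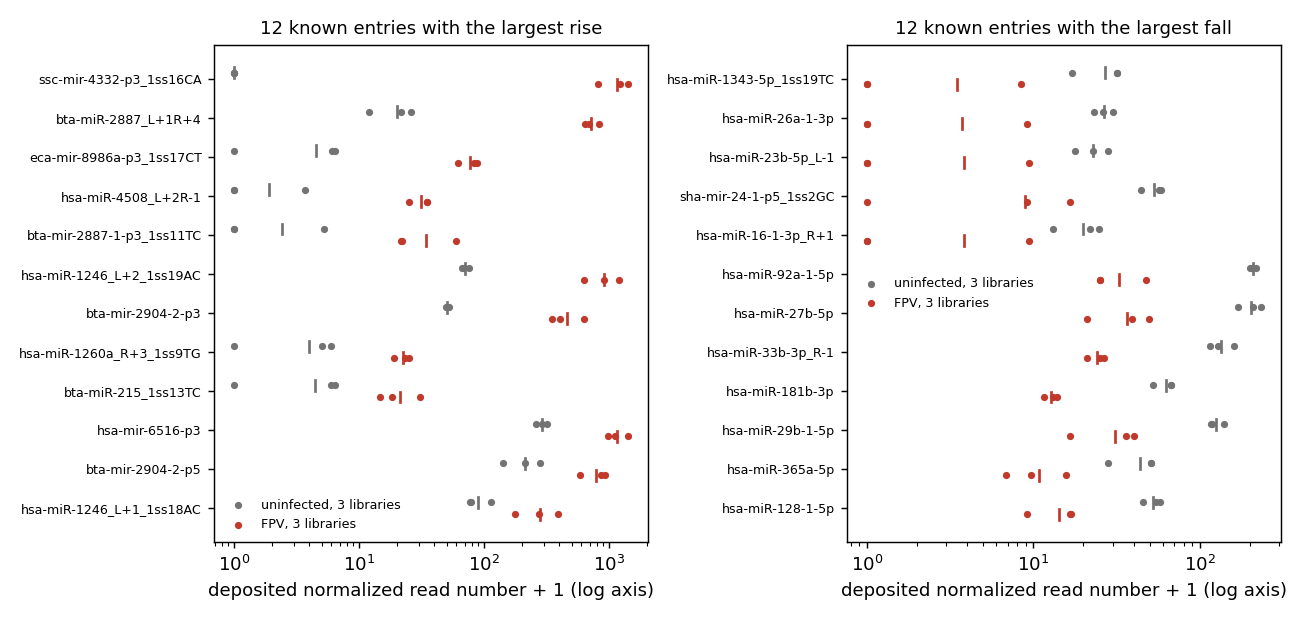
Normalized read number plus 1 (log x axis) of the 12 known entries with the largest rise (left) and the 12 with the largest fall (right), with points for single libraries of uninfected (grey) and FPV-infected cells (red), n = 3 each, and short vertical bars for group means. The groups do not overlap for any of the 24 entries, and ssc-mir-4332-p3_1ss16CA sits at 0 in every uninfected library.

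Among the 10 most abundant miRNAs, 8 did not pass the test. Besides miR-21-5p they were hsa-miR-100-5p at -0.23 (adjusted p = 0.140), hsa-miR-29a-3p_R-1 at 0.11 (adjusted p = 0.250), hsa-miR-221-3p_R-1 at 0.15 (adjusted p = 0.153), hsa-miR-222-3p_R+2 at -0.36 (adjusted p = 0.0930), hsa-let-7f-5p at 0.10 (adjusted p = 0.347), hsa-miR-125b-5p at -0.24 (adjusted p = 0.0543) and hsa-miR-143-3p_R+1 at -0.19 (adjusted p = 0.370), on the log2 scale. The entry hsa-miR-10b-5p_R-1, from the HOXD locus, fell by 0.79 on the log2 scale (SE 0.12), from 69198 ± 8619 to 40012 ± 4204 (adjusted p = 0.00314). The entry hsa-miR-92a-3p fell by 0.47 (SE 0.12, adjusted p = 0.0313). hsa-miR-92a-3p did not pass without uninfected replicates 1 or 2 or FPV replicate 1, under quantile normalization and with equal totals (adjusted p from 0.0548 to 0.213). hsa-miR-29a-3p_R-1 passed with equal totals (adjusted p = 0.0295). hsa-miR-222-3p_R+2 passed without FPV replicate 2 and under quantile normalization (adjusted p from 0.0347 to 0.0453). hsa-miR-125b-5p passed with a minimum of 50, with TMM scaling, with forms of a name summed and with entries of identical values fitted once (adjusted p from 0.0471 to 0.0498). hsa-miR-143-3p_R+1 passed without FPV replicate 3 (adjusted p = 0.0414). Under quantile normalization hsa-miR-125b-5p and hsa-miR-143-3p_R+1 were at 0.05 and 0.17.

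The miR-17-92 cluster and its paralogs, associated with proliferation, had 6 of 16 tested members lower, 2 higher and 8 that did not pass (2 higher and 6 lower when adjusted over the list alone). The entry hsa-miR-20a-5p was at 22610.4 ± 1691 in uninfected cells and 14372 ± 1254 in FPV-infected cells (SD, n = 3 each, adjusted p = 0.00306). Chosen after their values were seen, hsa-miR-19b-3p at -1.24 ± 0.20 and hsa-miR-19a-3p at -1.25 ± 0.24 (log2, SE) both fell (adjusted p = 0.00480 and 0.00901). In the opposite direction hsa-miR-106b-5p was at 0.46 ± 0.09 (adjusted p = 0.00848), and hsa-miR-17-3p_R-1 rose too (adjusted p = 0.0241), both also chosen after their values were seen. The largest falls in the list were those of the minor strands hsa-miR-92a-1-5p, at -2.74, and hsa-miR-25-5p_R+2, at -1.57, the second chosen after its values were seen. The major strand hsa-miR-25-3p was at 0.19 and did not pass (adjusted p = 0.298). The list passed in the downward direction at the preset correlation, though its members moved both ways (camera adjusted p = 0.0116, and adjusted p = 0.685 with an estimated correlation). The miR-17-92 list did not pass without FPV replicate 3, with forms of a name summed, with each distinct sequence fitted once and with entries of identical values fitted once (adjusted p from 0.0552 to 0.0738). hsa-miR-106b-5p did not pass without uninfected replicate 1 and under quantile normalization (adjusted p from 0.0559 to 0.0971). hsa-miR-17-3p_R-1 did not pass without uninfected replicates 1, 2 or 3 or FPV replicate 3 and under quantile normalization (adjusted p from 0.0522 to 0.257).

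The miR-99/100 and miR-125 group, transcribed together with let-7 members, had 3 of 11 lower and none higher (0 higher and 4 lower when adjusted over the list alone). The members that fell were hsa-miR-99b-5p and the minor strands hsa-miR-125b-1-3p and hsa-miR-125b-2-3p_L-2R+2, the last 2 chosen after their values were seen. The entry hsa-miR-125b-1-3p was at 1714 ± 198 in uninfected cells and 741 ± 17.6 in FPV-infected cells (SD, n = 3 each, adjusted p = 0.000286), while hsa-miR-100-5p and hsa-miR-125b-5p did not pass. The group passed in the downward direction at the preset correlation (camera adjusted p = 0.0116, and adjusted p = 0.685 with an estimated correlation). The miR-99/100 and miR-125 group did not pass under quantile normalization, with forms of a name summed and with entries of identical values fitted once (adjusted p from 0.0538 to 0.188). The miR-181 family had 3 of 8 lower and none higher (0 higher and 5 lower when adjusted over the list alone), all minor strands: hsa-miR-181a-3p, hsa-miR-181a-2-3p_1ss6TC and hsa-miR-181b-3p. Of the 8, 2 forms of miR-181a-5p have the same values in every library and may be the same reads, and with these fitted once 3 of 7 were lower (0 higher and 4 lower when adjusted over the list alone). The major strand hsa-miR-181a-5p was at 5319 ± 305 in uninfected cells and 4877 ± 1439 in FPV-infected cells (adjusted p = 0.584), and hsa-miR-181a-3p at 842 ± 90.5 in uninfected cells and 404 ± 38.1 in FPV-infected cells (adjusted p = 0.00147). The family, entered as 11 rows for its 8 distinct members, passed in the downward direction at the preset correlation (camera adjusted p = 0.0116, and adjusted p = 0.728 with an estimated correlation). The miR-181 family did not pass without FPV replicate 3, with forms of a name summed, with entries of identical values fitted once and by fry (adjusted p from 0.0538 to 0.0839). hsa-miR-99b-5p did not pass without uninfected replicates 1, 2 or 3 or FPV replicates 1 or 2, with no minimum and with equal totals (adjusted p from 0.0520 to 0.0949).

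The p53-responsive list holds miRNAs induced through p53 in the DNA damage response. Of its 10 tested members 4 rose and none fell, the same count when adjusted over the list alone. The entry hsa-miR-34a-5p_R+1, a direct p53 target, was at 881 ± 2.66 in uninfected cells and 1251 ± 77.2 in FPV-infected cells (SD, n = 3 each, adjusted p = 0.00885). The linked hsa-miR-192-5p and hsa-miR-194-5p rose by 0.67 and 0.81 on the log2 scale (SE 0.15 and 0.15, adjusted p = 0.0190 and 0.00873), and bta-miR-215_1ss13TC was at 3.45 ± 2.99 in uninfected cells and 20.2 ± 8.38 in FPV-infected cells (adjusted p = 0.0494). The most abundant member, hsa-miR-34c-5p, was at 1319 ± 167 in uninfected cells and 1322 ± 90.1 in FPV-infected cells (adjusted p = 0.979). The list as a whole did not pass (camera adjusted p = 0.0990, and adjusted p = 0.685 with an estimated correlation). The p53-responsive list passed without FPV replicate 1, with no minimum, with a minimum of 50, with known miRNAs only, without predicted entries at 0 in uninfected cells, without structured RNA names and by fry (adjusted p from 0.0130 to 0.0483, and adjusted p = 0.685 with all libraries and an estimated correlation). hsa-miR-34a-5p_R+1 did not pass without uninfected replicate 1 or FPV replicate 1 (adjusted p = 0.0520 and 0.0518). hsa-miR-192-5p did not pass without uninfected replicates 1 or 2 or FPV replicate 1 and under quantile normalization (adjusted p from 0.0697 to 0.273). bta-miR-215_1ss13TC did not pass without uninfected replicates 1 or 2, with a pseudocount of 0.5, with no minimum, under quantile normalization, with TMM scaling, with known miRNAs only, without predicted entries at 0 in uninfected cells and without structured RNA names (adjusted p from 0.0513 to 0.117).

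The kidney-enriched list moved both ways. Of its members miR-10b and miR-10a fell, with hsa-miR-10a-5p_R-1 at 20844 ± 2499 in uninfected cells and 13031 ± 808 in FPV-infected cells (SD, n = 3 each, adjusted p = 0.00386), while its p53-responsive members miR-192, miR-194 and miR-215 rose. Of 10 members 3 rose and 2 fell (3 higher and 3 lower when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.975), with a median of -0.15, a mean of 0.14 and a downward direction in the test. The miR-30 family, abundant in kidney epithelium, had 4 of 10 lower and none higher (0 higher and 5 lower when adjusted over the list alone). The entry hsa-miR-30d-5p_R+2 was at 29493 ± 3229.7 in uninfected cells and 20002 ± 2372 in FPV-infected cells (adjusted p = 0.0155), and hsa-miR-30e-5p_R+2 fell by 0.57 on the log2 scale (adjusted p = 0.0476). The minor strands hsa-miR-30d-3p and hsa-miR-30c-1-3p_1ss22CT, chosen after their values were seen, fell too (adjusted p = 0.0126 and 0.0132). The family as a whole did not pass (camera adjusted p = 0.0541). Of 14 members of the mesenchymal list 5 fell and none rose (1 higher and 5 lower when adjusted over the list alone), among them hsa-miR-145-5p, chosen after its values were seen, at -1.09 ± 0.19 (adjusted p = 0.00703). The others were hsa-miR-10b-5p_R-1 and, also chosen after their values were seen, hsa-miR-145-3p_R-1, mdo-miR-21-5p_L+2R+1 and hsa-miR-143-5p_R-1 (adjusted p = 0.00720, 0.0266 and 0.0365). Of these, hsa-miR-145-3p_R-1 and hsa-miR-143-5p_R-1 are minor strands, and mdo-miR-21-5p_L+2R+1 is a rare form of miR-21. The mesenchymal list as a whole did not pass (camera adjusted p = 0.215). The miR-30 family passed without uninfected replicate 2 or FPV replicate 2, with no minimum and with a minimum of 50 (adjusted p from 0.00833 to 0.0483, and adjusted p = 0.728 with all libraries and an estimated correlation). hsa-miR-30d-5p_R+2 did not pass without uninfected replicates 1 or 3 or FPV replicate 1 (adjusted p from 0.0523 to 0.0678). hsa-miR-30e-5p_R+2 did not pass without uninfected replicates 1 or 3 or FPV replicates 1 or 3, with a pseudocount of 0.5, with no minimum, with TMM scaling, with equal totals, without predicted entries at 0 in uninfected cells and without structured RNA names (adjusted p from 0.0508 to 0.143). hsa-miR-30d-3p did not pass without uninfected replicate 1 (adjusted p = 0.0580). hsa-miR-30c-1-3p_1ss22CT did not pass without uninfected replicate 2 or FPV replicate 1 (adjusted p = 0.0668 and 0.0560). mdo-miR-21-5p_L+2R+1 did not pass without uninfected replicates 1, 2 or 3 or FPV replicate 1 and with equal totals (adjusted p from 0.0507 to 0.0914). hsa-miR-143-5p_R-1 did not pass without uninfected replicates 1, 2 or 3 or FPV replicate 1, with no minimum and with equal totals (adjusted p from 0.0507 to 0.111).

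The NF-kB and innate response list had 1 of 19 members higher and 5 lower (1 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.204). The one that rose was hsa-miR-146a-5p, a target of NF-kB, at 0.28 ± 0.08 (log2, SE, adjusted p = 0.0422). Those that fell were hsa-miR-125b-1-3p, hsa-miR-125b-2-3p_L-2R+2, mdo-miR-21-5p_L+2R+1, hsa-miR-221-5p_R+2_1ss21TA and hsa-miR-222-5p_L+2R-1, the last at 236 ± 36.9 in uninfected cells and 66.2 ± 26.4 in FPV-infected cells (SD, n = 3 each, adjusted p = 0.00386). All 6 were chosen after their values were seen. The interferon-linked list had 1 of 12 lower, the minor strand hsa-miR-29b-1-5p, and none higher (camera adjusted p = 0.975, the same count when adjusted over the list alone). The abundant hsa-miR-29a-3p_R-1 was at 210957 ± 8254 in uninfected cells and 227813 ± 7222 in FPV-infected cells. In the hypoxia and stress list 3 of 14 fell and none rose, the same count when adjusted over the list alone. The hypoxia-induced hsa-miR-210-3p was at 4394 ± 455 in uninfected cells and 2957 ± 191 in FPV-infected cells (adjusted p = 0.00891), and the list did not pass (camera adjusted p = 0.204). The others that fell were hsa-miR-182-5p (adjusted p = 0.0354) and the minor strand hsa-miR-193b-5p, chosen after its values were seen (adjusted p = 0.00184). The NF-kB list passed with no minimum (adjusted p = 0.0214, and adjusted p = 0.950 with all libraries and an estimated correlation). hsa-miR-146a-5p did not pass without uninfected replicates 1, 2 or 3 or FPV replicates 1, 2 or 3, with no minimum, with TMM scaling, with known miRNAs only, without predicted entries at 0 in uninfected cells and without structured RNA names (adjusted p from 0.0507 to 0.149). hsa-miR-210-3p did not pass without uninfected replicate 1 or FPV replicate 1 (adjusted p = 0.0520 and 0.0519). hsa-miR-182-5p did not pass without uninfected replicates 1 or 3 or FPV replicates 1 or 3, with no minimum and with equal totals (adjusted p from 0.0518 to 0.124).

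The let-7 family had 1 of 22 members higher and 2 lower (0 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.720), with a median of 0.04, a mean of -0.20 and a downward direction in the test. Under quantile normalization the median was -0.27. None of its 4 most abundant members passed, with hsa-let-7i-5p at 43601 ± 1259 in uninfected cells and 50121 ± 4487 in FPV-infected cells (SD, n = 3 each, adjusted p = 0.124). Chosen after their values were seen, hsa-miR-98-5p rose and the minor strands hsa-let-7b-3p_1ss22CT and hsa-let-7a-3p_R+1 fell (adjusted p = 0.0385, 0.0116 and 0.00848). hsa-miR-98-5p did not pass without uninfected replicates 1, 2 or 3 or FPV replicates 1, 2 or 3, with no minimum, under quantile normalization, with TMM scaling and without predicted entries at 0 in uninfected cells (adjusted p from 0.0510 to 0.162). hsa-let-7b-3p_1ss22CT did not pass without uninfected replicate 1 or FPV replicate 1 (adjusted p = 0.0678 and 0.0518). hsa-let-7i-5p passed under quantile normalization and with equal totals (adjusted p = 0.00162 and 0.0189). hsa-let-7g-5p passed under quantile normalization (adjusted p = 0.0133). In the miR-15/16 family, which shares a seed that pairs with cyclin transcripts, 2 of 15 rose and 3 fell (2 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.967). The median was 0.00278, the mean -0.34 and the direction in the test downward. The entry hsa-miR-15b-5p was at 6096 ± 539 in uninfected cells and 10053 ± 1103 in FPV-infected cells (adjusted p = 0.00386), and hsa-miR-424-5p_R-1 rose too (adjusted p = 0.0277). With hsa-miR-16-1-3p_R+1, the variant dno-miR-503-5p_R+2 and the minor strand hsa-miR-195-3p_1ss22CT fell, both chosen after their values were seen (adjusted p = 0.0126 and 0.0143). In the miR-23/24/27 clusters 2 of 10 rose and 4 fell (3 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.975). Among the major strands, hsa-miR-27a-3p_R-1 at 10421 ± 897 in uninfected cells and 16263 ± 2809 in FPV-infected cells rose (adjusted p = 0.0146) and so did hsa-miR-24-3p_R-2 (adjusted p = 0.0266). Those that fell were the minor strands hsa-miR-27a-5p (chosen after its values were seen), hsa-miR-27b-5p, sha-mir-24-1-p5_1ss2GC and hsa-miR-23b-5p_L-1. hsa-miR-27a-3p_R-1 did not pass without uninfected replicate 1 or FPV replicate 1 (adjusted p = 0.0646 and 0.0541). hsa-miR-24-3p_R-2 did not pass without uninfected replicates 1 or 2 or FPV replicates 1 or 2 and under quantile normalization (adjusted p from 0.0663 to 0.121). hsa-miR-424-5p_R-1 did not pass without uninfected replicates 1, 2 or 3 or FPV replicates 1 or 2 and under quantile normalization (adjusted p from 0.0663 to 0.190). dno-miR-503-5p_R+2 did not pass without uninfected replicate 1 or FPV replicate 1 (adjusted p = 0.0606 and 0.0518). hsa-miR-195-3p_1ss22CT did not pass without uninfected replicate 3 or FPV replicate 1 (adjusted p = 0.0527 and 0.0552).

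Markers of other cell types varied between the libraries of each group. The red blood cell miRNA hsa-miR-451a_R-1 was at 0, 198 and 645 in uninfected replicates 1 to 3 and at 1052, 109 and 837 in FPV replicates 1 to 3 (adjusted p = 0.347). The liver miRNA hsa-miR-122-5p_R-1 was at 9.37, 127 and 369 and at 637, 283 and 414 (adjusted p = 0.174). Of 7 haematopoietic entries none passed, at a median of 2.19 on the log2 scale (0.80 to 3.55 with a library left out, camera adjusted p = 0.211). Folds of their group means ran from 2.07 to 4.05. A library at 0, such as uninfected replicate 1 for hsa-miR-451a_R-1, widens the difference on the log2(value + 1) scale. FPV replicate 2 stood apart from the other 5 libraries. It listed 51 entries of the 14q32 list above 0, against 3 to 5 in each other library, and 46 of them in no other library. Without miR-342 and miR-345, which lie outside the imprinted cluster there, the numbers were 47 and 0 to 1. The epithelial hsa-miR-200c-3p was at 441 in FPV replicate 2 and at 5.92 to 14.1 in the other libraries. Of 3 tested 14q32 entries, all miR-342 or miR-345, none passed (camera adjusted p = 0.961), so at the minimum used that test does not cover the cluster. The muscle list had 1 of 3 lower (hsa-miR-133a-5p) and the neural list 1 of 8 lower (hsa-miR-128-1-5p), with camera adjusted p = 0.694 and 0.694. Both entries that fell are minor strands. The muscle list had a median of 0.08, a mean of -0.31 and a downward direction in the test. The neural list had a median of 0.11, a mean of -0.28 and an upward direction in the test. The haematopoietic list passed without uninfected replicate 3 or FPV replicate 2 and with no minimum (adjusted p from 0.0178 to 0.0214, and adjusted p = 0.979 with all libraries and an estimated correlation). hsa-miR-133a-5p did not pass without uninfected replicates 1, 2 or 3 or FPV replicates 1 or 3, with no minimum and with equal totals (adjusted p from 0.0516 to 0.113).

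Whether the strands of a hairpin changed unequally was asked with the 5p to 3p ratio inside each library, which needs no scaling between libraries. FPV-infected cells had relatively less of the minor strand in many hairpins. For miR-27a the 5p strand was at 259.9 ± 71.7 in uninfected and 73.7 ± 8.62 in FPV-infected cells, while the 3p strand was at 10421 ± 897 and 16263 ± 2809 (SD, n = 3 each). The log2 ratio changed by -2.41 ± 0.20 (SE, limma adjusted p = 0.00372). For miR-25 and miR-27b the changes were -1.77 ± 0.17 and -2.78 ± 0.28 (adjusted p = 0.00372 and 0.00372), and for miR-193b and miR-128 they were -1.45 and -2.21 (adjusted p = 0.00382 for each). In miR-181b, whose minor strand is 3p, the 5p to 3p ratio rose by 1.93 ± 0.24 (adjusted p = 0.00608). Of 120 hairpins 30 changed, 25 toward the more abundant strand and 5 toward the less abundant one (miR-339, miR-28, miR-17, miR-8986a and miR-1246). The 120 include miR-1246, miR-2904 and miR-6240, whose names overlap structured RNAs and may not stand for miRNA hairpins. Of these only miR-1246 changed. With entries of identical values summed once the miR-1246 5p strand was the more abundant one, and 26 of 30 changed hairpins went toward the more abundant strand. In 84 of the 120 the minor strand was relatively lower, with a median of -0.31 on the log2 scale over the 120. The 84 include 5 hairpins (miR-322, miR-382, miR-409, miR-411 and miR-434) listed only in FPV replicate 2. These have no uninfected ratio, and their minor strand is relatively lower by definition. The count of changed hairpins was 6, 11 and 7 without uninfected replicates 1, 2 and 3, and 18 and 14 without FPV replicates 1 and 2. Of those, 6, 8, 7, 15 and 13 changed toward the more abundant strand.

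**Figure D3:**
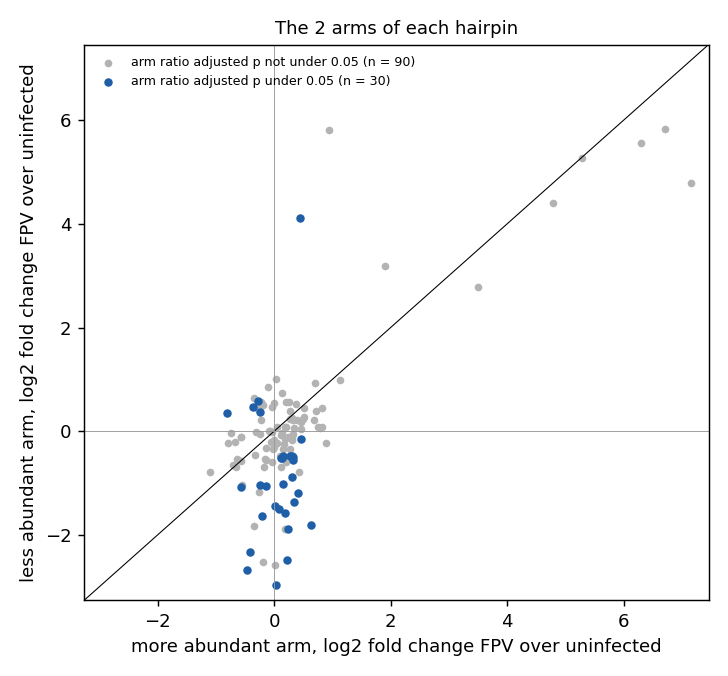
Each point is 1 of 120 hairpins, with the log2 fold change (FPV over uninfected group means) of its more abundant strand on the x axis and of its less abundant strand on the y axis, and the 30 blue points passed the arm ratio test. Points below the diagonal have a relatively lower minor strand in FPV-infected cells, and 5 hairpins at the upper right had over 90% of their reads in FPV replicate 2 alone, and none of them passed.

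The makeup of the libraries was described by the share held by 3 classes. The 10 most abundant miRNAs held 65.9% ± 0.461 of normalized reads in uninfected cells and 63.2% ± 1.15 in FPV-infected cells (SD, n = 3 each). The let-7 share was 7.26% ± 0.324 and 8.33% ± 0.210. Predicted sequences held 0.184% ± 0.0104 and 0.436% ± 0.0759. For each of the 3 shares the groups did not overlap, and the two-sided exact permutation p was 0.1 (adjusted p = 0.1), the smallest that 3 libraries against 3 allow.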

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

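The fits of distinct sequences, of entries with identical values once, without predicted entries listed at 0 in uninfected cells and of known entries without structured RNA names were chosen after the data were seen. The count of 142 changed entries stayed within 1.5 times under every alternative except the following. It was 83 for known entries without structured RNA names, where fewer entries were tested, 79 without uninfected replicate 1 and 58 without FPV replicate 1. All fits with a library left out gave 58 to 104 (15 to 63 higher and 31 to 67 lower). With an FPV library left out, the 30 predicted and 1 known entries listed at 0 in all uninfected libraries could not be tested. The number higher was 37 with known miRNAs only, 37 without predicted entries listed at 0 in uninfected cells and 27 without structured RNA names, since those entries are among the higher ones. Quantile normalization shifted the median of all entries by -0.11 on the log2 scale, and equal totals by 0.09. Replicate numbers did not pair the libraries: same-numbered libraries had correlations of -0.15, 0.05 and 0.08 of their deviations. With the replicate number as a block the count was 97, with 53 higher and 44 lower, 3 lists were called and 7 hairpins changed, 6 of them toward the more abundant strand. With the block 22 of the 75 named calls were lost, and these losses are not listed beside the single results. The number of lists called was 3, against 8 with no minimum, 5 with a minimum of 50, 0 with forms of a name summed, 0 with entries of identical values fitted once, 0 with an estimated correlation and 1 to 5 with a library left out. Changed hairpins numbered 6 to 32 with a library left out, 6 to 27 of them toward the more abundant strand, and the median of the minor strand ran from -0.35 to -0.28. Shares kept their direction with each library left out: differences ran from -3.23 to -1.86 percentage points for the 10 most abundant, 0.92 to 1.24 for let-7 and 0.22 to 0.29 for predicted entries. Of 119 named entries 103 kept their direction in every fit that held them, and of 75 called ones 37 stayed called in every such fit. Single results fell short of the threshold in 192 fits and newly passed in 39. Entries and lists that changed direction are given as log2 values, for lists as the median beside a change in the direction of the test, and the cause was not tested. With a pseudocount of 10: the kidney-enriched list -0.15. With no minimum: the interferon-linked list 0.11, the kidney-enriched list 0.0540 and the 14q32 list 1.74. With a minimum of 50: the miR-15/16 family list 0.0899, the interferon-linked list 0.16, the kidney-enriched list -0.15 and the miR-23/24/27 clusters list 0.0987. Under quantile normalization: hsa-miR-125b-5p 0.0477, hsa-miR-143-3p_R+1 0.17, bta-miR-345-5p_R+1 -0.19, hsa-miR-133a-3p_R+1 -0.00808, hsa-miR-9-3p -0.14, hsa-miR-138-5p -0.12, the let-7 family list -0.27 and the kidney-enriched list -0.20. With TMM scaling: hsa-miR-34c-5p -0.0111 and hsa-miR-138-5p -0.0109. With known miRNAs only, without predicted entries at 0 in uninfected cells and by fry: the miR-15/16 family list 0.00278, the interferon-linked list -0.00651, the kidney-enriched list -0.15 and the miR-23/24/27 clusters list -0.18. With forms of a name summed: hsa-miR-1260a_R+3_1ss9TG -0.44, bta-mir-1246-p5 0.38 and the neural list 0.11. With each distinct sequence fitted once and with entries of identical values fitted once: the neural list 0.11. With equal totals: bta-miR-503-5p_R+3 0.0734, bta-miR-345-3p_L+1R+1 0.0479, hsa-miR-99a-5p_R-1 0.0293 and the interferon-linked list 0.0826. Without structured RNA names: the let-7 family list 0.0438, the miR-15/16 family list 0.00278, the interferon-linked list -0.00651, the kidney-enriched list -0.15 and the miR-23/24/27 clusters list -0.18. With a library left out, those that changed direction ranged as follows: hsa-let-7g-5p -0.0454 to 0.0783, bta-miR-503-5p_R+3 -0.11 to 0.0492, hsa-miR-34c-5p -0.0981 to 0.0817, hsa-miR-196b-5p -0.19 to 0.0205, bta-miR-345-3p_L+1R+1 -0.14 to 0.0356, hsa-miR-99a-5p_R-1 -0.11 to 0.0263, hsa-miR-181a-5p -0.38 to 0.0445, hsa-miR-1-3p -0.0846 to 0.22, hsa-miR-133a-3p_R+1 -0.21 to 0.55, hsa-miR-138-5p -0.15 to 0.12, the let-7 family list -0.12 to 0.0641, the miR-15/16 family list -0.0314 to 0.11, the interferon-linked list -0.0535 to 0.0437, the kidney-enriched list -0.24 to -0.10, the 14q32 list -0.14 to 0.0356, the miR-23/24/27 clusters list -0.33 to 0.0144 and the muscle list -0.21 to 0.22. Raw counts were not recovered, so RLE and upper quartile factors and the count-based tests planned for raw counts were not run. Depth limits entries near the smallest listed value, where a 0 in an FPV library may stand for a value under the 2.11 to 2.91 that is the smallest listed there.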

Other observations

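The tests of depth and of GC content for predicted entries found only in FPV libraries, and the test of structured RNA breakdown with its bound, were chosen after the result was seen. Intervals given below come from resampling entries with the 6 libraries held fixed, so they do not measure the spread between flasks. Between libraries, haematopoietic entries held 0.00248, 0.0120 and 0.0363 percent of normalized reads in uninfected replicates 1 to 3 and 0.0659, 0.0126 and 0.0519 percent in FPV replicates 1 to 3. The 14q32 list held 0.227 percent in FPV replicate 2 and 0.0292 to 0.0483 percent in the others, and the miR-200 list 0.132 percent against at most 0.000451 percent. RNA from another sample in FPV replicate 2 was not tested for and is not excluded, and the FPV means and SDs include this library. Leaving it out gave 103 changed entries.

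The 142 changed entries compare with a highest count of 0 in the other 9 splits of the 6 libraries by limma, where between 1 and 26 passed at an unadjusted p of 0.05. Only 1 split, the real one, gave as many, and 10 splits are too few for a share under 0.05. Each of the other 9 splits mixes infected and uninfected libraries, so any difference between the 2 adds to the spread and lowers the count. Their counts thus do not show what chance alone would give.

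In 84 of 120 hairpins the minor strand was relatively lower in FPV-infected cells, counting 5 listed only in FPV replicate 2, where this holds by definition. Within these 6 libraries the values argue against GC content and length as the cause. With both and abundance in a model, minor strands stayed at -0.52 on the log2 scale (95% interval over entries -0.75 to -0.27) beside other known entries. Fewer newly made hairpins in infected cells, a biological candidate explanation, stay open: minor strands had a median of -0.11 (-0.29 to 0.0775) where they are 3p and -0.19 (-0.57 to 0.0350) where they are 5p. The bound set in advance, an interval that reaches 0, was too loose, since these intervals hold both falls and no change. The lower depth of the FPV libraries stays open: at a mean of at least 50 minor strands differed from entries of matched abundance by -0.44, with an interval from -0.64 to -0.0891 that excludes 0 but reaches past the bound of -0.2 set for ruling depth out.

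A set of 45 predicted sequences was found only in FPV libraries. Lower depth argues the other way, since among predicted entries the shallower group had 9 times as many of its own as the deeper one (45 against 5). Known entries went the other way, with 6 found only in FPV and 14 only in uninfected libraries, as lower depth would give. RNA from another organism brought with the inoculum, the virus included, may be the source of the 45 predicted ones: their GC content differed by -11.7 percentage points from that of other predicted entries (95% interval -15.2 to -8.3, permutation p = 2.0e-05). A cellular source of low GC content would give the same difference, so the 2 cannot be told apart without a match to a viral and a cat genome, not analysed here.

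Entries that overlap structured RNAs had class means of 1.98 ± 0.26 for ribosomal, 0.47 ± 0.21 for small nuclear and nucleolar and 0.56 ± 0.34 for transfer RNA (log2, SE between libraries, permutation p = 0.1, 0.2 and 0.2, where 0.1 is the smallest possible). The first 2 lie above 0 by more than 2 SE, and the share of the small nuclear and nucleolar class was 0.0362% in uninfected and 0.101% in FPV-infected cells, though 6 of its 11 entries lay below 0. A general breakdown of structured RNA, a hypothesis drawn from these values, needs all 3 above 0. It stays open, since the transfer RNA mean lies within 2 SE of 0 and the share of that class was 0.0322% and 0.0307%. Shorter inserts in the FPV libraries stay open: other known entries of 20 bases or fewer differed from longer ones by 0.26, with an interval from -0.00306 to 0.54, which includes 0 and reaches past the bound of 0.2.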
